A study of Mus musculus with 93 samples.

How the data were processed

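Gene expression was measured in 93 single-cell libraries of mouse lung, 54 labelled Tbx4 lineage+ and 39 labelled Tbx4 lineage-. Per the labels' protocols, cells were captured on Fluidigm C1 chips, wells were inspected by eye to remove empty wells, doublets and debris, cDNA was made with a SMARTer kit, and libraries were made with Nextera XT and sequenced as single-end reads. Doublets were not called again here. The submitters' processing notes name Bowtie 1.1.1, RSEM 1.2.20 and the builds GRCm38 and mm9, without saying which step used which. Per the file headers, the tables have the layout of a Cufflinks gene table, and the step that made them is not given in the sources used here.

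The deposited values are FPKM per gene and cell, in 1 table per group. The unit is inferred: no label or header names it, the values are not whole, and totals differ between cells, with medians of 288286 over kept lineage+ and 327392 over kept lineage- cells. The design was written to take counts or FPKM, and the FPKM branch was used. Of 23846 gene rows, 1830 (7.67%) held a dash, a transcription start identifier or a locus in place of a value and were not used. Tbx4, Pdgfra and Ptprc are among them. A further 731 rows of 249 symbols that occur more than once were left out, which leaves 21285 genes. In 1 row the symbols of both tables differ at the same locus, and it was taken as Actb from its coordinates. Of 19783 symbols also in GENCODE M21 (GRCm38), 99.4% overlapped the annotated gene. The RefSeq start was the file's start plus 1 for 11207 of 19613 symbols and equal to it for 640, so starts are printed with 1 added. Paralogs and overlapping genes may share reads, and how such reads were divided is not given in the sources used here.

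Depth was estimated because FPKM keep no counts. Values of genes with 1 annotated transcript, multiplied by its length, fall in steps of what 1 read is worth. The estimator is the last of 3 versions, each adjusted after looking at these cells. On 60 simulated cells it came within 2-fold in 59 and failed in 1, with a log2 error of 5.75, so a single cell's depth can be wrong. It was used to describe depth, for an added alternative and for the tests of shallow sequencing. Depths per cell are therefore approximate, and no interval was given for a depth. The tests that select cells by it carry this uncertainty, which their intervals leave out.

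Profiles were compared pairwise by Pearson r on log2 of FPKM plus 1. The 2 pairs above 0.9, both in lineage+, were averaged and counted once, which leaves 91 cells. The comparison was made and that rule set after the results with every profile counted had been seen, and the profiles counted separately are an alternative.

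A gene was called detected at 1 FPKM. Cells with at least 1000 detected genes were kept. The level of a gene in a group was the mean over its kept cells, and the log2 ratio was taken after adding 1 to both groups, which understates the change of low genes. Shares have exact Clopper-Pearson 95% intervals. Since each group counts as 1 sample, no p-value, standard error or count of changed genes was made. The median log2 ratio of each of 21 gene lists and 14 marker lists was taken over members detected in at least 10% of cells of either group. It was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stands apart outside the central 95% of them. For a simulation both groups were drawn from the kept lineage+ cells, with changes planted in genes detected in at least 50% of them. All 54, 46, 50 and 50 genes planted at log2 ratios of -3, -2, 2 and 3 had the right direction among 21285 genes. Their median ratios were -2.94, -1.82, 1.86 and 2.78. Genes detected in fewer cells, and groups that differ in cell classes or depth, were not simulated. A planted list lay at percentile 100, and 1 of 100 unchanged lists stood apart, both among 7353 genes. The simulated lists held widely detected genes drawn at random, which leaves untested how the percentile behaves for lists whose members vary together.

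Cells of both groups were clustered together on log2 of values scaled to a total of 1000000, plus 1, with scanpy 1.11.5 and igraph 0.11.9 (2000 variable genes, 15 components, 10 neighbours, Leiden at resolution 1, seed 0). A cluster took the class whose markers stood highest in it against all other cells, if at least 3 were detected in 30% of its cells. The markers were fixed before the data were examined. This naming rule, and the grouping of marker lists into broad classes (alveolar, adventitial and myofibroblast lists as fibroblast; the 4 epithelial lists as epithelial), were set after clusters had been seen. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

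Named genes followed a rule fixed before the data were examined. It took the lineage and sort markers; the 12 highest and 12 lowest log2 ratios among genes detected in at least 50% of cells of the higher group whose mean scaled value and mean log2 level differed the same way; and up to 4 members of each list with the largest ratios among those detected in 25% of cells of either group. Ribosomal protein, predicted and pseudogene rows were left out. The Y-linked genes named lie outside this rule and were chosen as members of the sex chromosome list. Alternatives covered the cells kept, the detection threshold, the mean, the pseudocount, the scaling, the list filter and the clustering. Added after seeing the data were the cells with an estimated 2000000 reads or more, the repeated profiles counted separately and a class for each cell from its own markers without clustering.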

Results

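The data were single-cell RNA-seq profiles of cells sorted from the lungs of adult C57BL/6 mice in which Cre recombinase driven by Tbx4, a T-box transcription factor gene of the developing lung mesenchyme, switches on a heritable reporter. Each library was meant to hold 1 cell caught on a Fluidigm C1 chip. The labels put 54 libraries in the Tbx4 lineage+ group and 39 in the Tbx4 lineage- group. Capture sites were all different within a group (54 and 39 sites) and the cells of each group carried 1 name prefix of their own, 7m-Lung for lineage+ and Tbx4-2 for lineage-. No label says what the prefixes mean or names a chip or an animal, so lineage group cannot be told apart from chip, animal or preparation. Each group was therefore taken as 1 sample, the difference between groups has no replicate check, and the intervals given cover counting error over cells only.

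All libraries were compared in pairs, after the group means had been seen. Lineage+ cells 2 and 15 had nearly the same profile (Pearson r of 0.996 over log2 values of all genes), as did lineage+ cells 9 and 23 (0.997), while no other of the 4278 pairs exceeded 0.596. They shared 1622 of 1687 and 2530 of 2640 detected genes. Their differences were 4.68 and 8.12 times the counting noise expected from roughly estimated reads, against at least 58.9 times for other pairs within a group, and no value above the detection threshold was identical. The pairs thus differed by more than the estimated counting noise but by far less than any other pair within a group, and each was averaged and counted as 1 cell, which leaves 52 lineage+ and 39 lineage- cells.

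Cells with at least 1000 genes at 1 FPKM or more were kept, 50 lineage+ and 34 lineage-. The median number of genes detected was 2412.5 in lineage+ cells (quartiles 1792.5 and 2825.75) and 1812 in lineage- cells (quartiles 1450.5 and 2192.75). The deposited values hold no read counts, but steps among the low values put the median depth of kept cells near 6800000 reads in lineage+ (quartiles 5590000 and 8260000) and 7860000 in lineage- (quartiles 3860000 and 9940000). This is a rough estimate, within 2-fold in 59 of 60 simulated cells and not checked on cells of known depth. The lowest estimate in lineage+ was 2290000 reads, while 6 of the 34 kept lineage- cells were under 2000000 and the lowest stood at 155000. The 2 groups were deposited as separate tables, and whether they were scaled together is not given in the sources used here. This holds for every level set across the groups. Over 999 genes detected in at least 50% of kept cells, the median log2 ratio of lineage+ over lineage- was 0.12. Setting that shift to 0 moves every gene alike, so it cannot change a list's place among random lists, and it turned the direction of none of the 124 named genes.

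The first comparison was of the markers of lineage and sort, which check the labels. The series design calls both groups mesenchymal, whereas the protocol label writes the gate as positive for Epcam, an epithelial adhesion molecule, and negative for CD31 and CD45. Epcam (chromosome 17, 87635979 to 87651127, GRCm38) was detected in 12 of 34 lineage- cells (35.3%, exact 95% interval 19.7 to 53.5%) and in 1 of 50 lineage+ cells (2%, 0.0506 to 10.6%). Its mean was 42.6 FPKM in lineage- and 6.29 FPKM in lineage+ cells, the latter carried by lineage+ cell 27 at 314.5 FPKM. Lineage- cell 8 at 1042 FPKM carried most of the lineage- mean, and the lineage- median was 0.387 FPKM. Among cells with at least 2000 genes the log2 ratio of Epcam turned from -2.58 to 1.48. That set leaves out lineage- cell 8 (1307 genes) and keeps lineage+ cell 27 (2134 genes). Pecam1, which encodes CD31, was listed at 0 in all 50 and 34 kept cells. With detection at any value above 0 the share for Epcam in lineage- was 64.7%, and at 10 FPKM it was 14.7%. Pdgfrb, a receptor of pericytes and fibroblasts, was detected in 17 of 50 lineage+ cells (34%, 21.2 to 48.8%) and 1 of 34 lineage- cells (2.94%, 0.0744 to 15.3%). Tbx4 itself, Ptprc (CD45) and Pdgfra had rows without values, and the tables used here held no reporter row, so the lineage label could not be checked against them.

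The cells were then clustered on their most variable genes, to ask which cell types each sort held. Clusters were named from marker lists fixed before the data were examined, by a rule set after clusters had been seen. Most lineage+ cells were fibroblast-like, 40 of 50 (80%, 66.3 to 89.97%), and the remaining 10 were mesothelial-like (20%, 10.0 to 33.7%). Lineage- cells were mostly epithelial-like, 19 of 34 (55.9%, 37.9 to 72.8%), or immune-like, 11 of 34 (32.4%, 17.4 to 50.5%). Fibroblast-like cells made up 3 of 34 lineage- cells (8.82%, 1.86 to 23.7%) and a single lineage- cell was mesothelial-like (2.94%, 0.0744 to 15.3%). No lineage+ cell was epithelial-like or immune-like, with an upper bound of 7.11% for each. The classes rest on the same genes that differ between the groups, and a class held by 1 group cannot be told from that group's chip or preparation. The gate as written would exclude CD45-positive immune cells, and Ptprc had no values with which to check the 11 immune-like cells. Ward clustering put all 10 lineage+ mesothelial-like cells with the fibroblast-like, clustering each group on its own named 40% of lineage+ and 0% of lineage- cells fibroblast-like. A class for each cell from its own markers called 5 of the 11 immune-like cells epithelial-like, with 17.6% of lineage- cells then immune-like and 67.6% epithelial-like, and among the 12 lineage- cells with at least 2000 genes 0% were epithelial-like and 75% immune-like. Lineage- cell 5, which carried fibroblast, epithelial and immune markers, was immune-like here and fibroblast-like when the repeated profiles were counted separately.

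**Figure D1:**
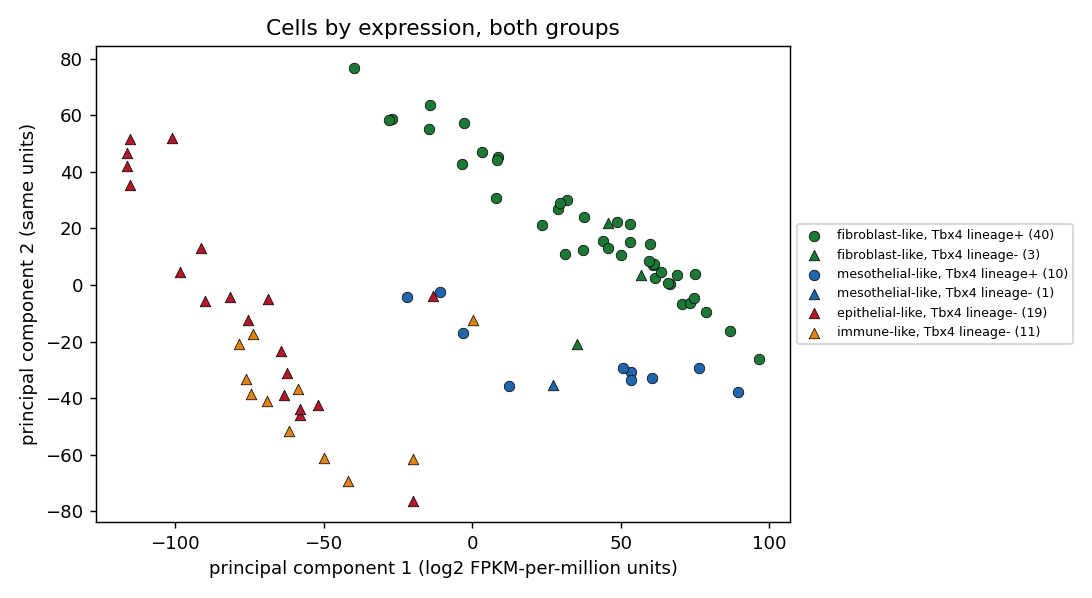
First and second principal components of the 2000 most variable genes over the 84 kept cells, on log2 values, with circles for lineage+ and triangles for lineage- cells, coloured by class. Most epithelial-like lineage- cells lie at low values of the first component, but epithelial-like lineage- cell 1 lies among lineage+ mesothelial-like cells.

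**Figure D2:**
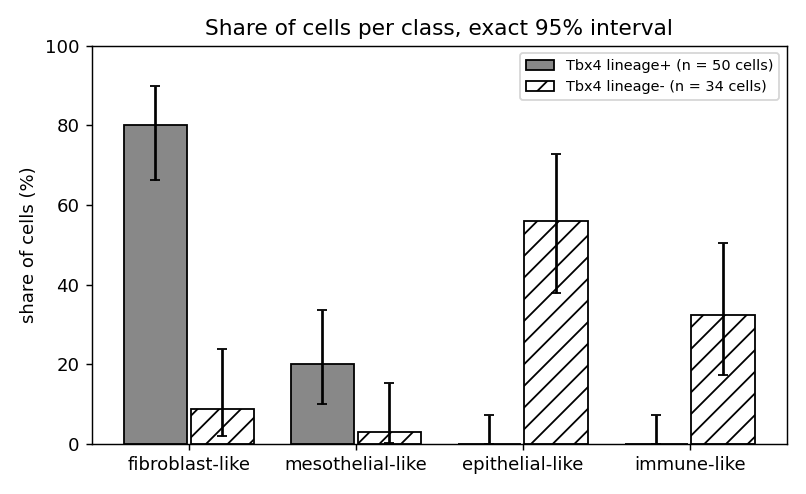
Share of kept cells in each class (%, bars from 0), with exact 95% binomial intervals as error bars that cover counting error only. Grey bars are the 50 lineage+ cells and hatched bars the 34 lineage- cells.

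The fixed rule ranks only genes detected in at least 50% of cells of the higher group. Among its 12 genes with the largest ratios in lineage+ cells, Tcf21 and Itga8 belong to the alveolar fibroblast list and the others to no fibroblast marker list. Genes detected in fewer cells fall outside it, such as the mesothelial marker Upk1b (5.75) and the myofibroblast marker Mustn1 (4.99). Tcf21, a transcription factor of lipid-bearing alveolar fibroblasts (chromosome 10, 22817275 to 22820128), had a mean of 92.9 FPKM in lineage+ and 0.0141 FPKM in lineage- cells, and was detected in 31 of 50 and 0 of 34 cells. Its log2 ratio of 6.53 was the largest by the fixed rule. Itga8, an integrin subunit, stood at 37.8 against 0.559 FPKM (log2 ratio 4.64). Mmp2, a gelatinase, stood at 122 against 4.01 FPKM (4.62) and was detected in 38 of 50 lineage+ and 3 of 34 lineage- cells. Nox4, an NADPH oxidase, stood at 27.8 against 0.0537 FPKM (4.77), Spon2 at 156 against 4.15 (4.93) and Il6, an inflammatory cytokine, at 337 against 12.8 FPKM, detected in 26 of 50 and 6 of 34 cells. Nop58, Ptp4a1, C1rb, Gng11, Tgfbr3 and Sc5d completed the 12, with log2 ratios from 4.36 to 5.19. With all 91 cells the ratio of Ptp4a1 turned to -0.63. Without the highest cell of each group Gng11 moved from 4.48 to 5.97. Among cells with at least 2000 genes Sc5d stood at 2.65, Gng11 at 3.10, Spon2 at 3.41 and Ptp4a1 at 6.74.

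By the same rule, the 12 genes with the largest ratios in lineage- cells included members of the alveolar type 2, type 1, airway and immune marker lists. Sftpc, the surfactant protein C gene of alveolar type 2 cells (chromosome 14, 70520942 to 70524081), had a mean of 31872 FPKM in lineage- and 3.60 FPKM in lineage+ cells, a log2 ratio of -12.76. Sftpc was also listed at exactly 0 in 6 of 10 lineage- cells rich in other type 2 markers, and the 2 kept cells with the lowest estimated depths, lineage- cells 34 (512389 FPKM) and 17 (368330 FPKM), carried most of the lineage- mean. Lineage+ cell 4 (155 FPKM) carried most of the lineage+ mean. The ratio was -10.43 over cells with an estimated 2000000 reads or more, and it ranged from -13.49 to -5.25 over the alternatives tried. Ager, a type 1 cell receptor, stood at 3248 FPKM in lineage- against 0.0177 FPKM in lineage+ (log2 ratio -11.64), with 25 of 34 lineage- cells and 0 of 50 lineage+ cells detecting it. Lyz2, a lysozyme of myeloid and type 2 cells, stood at 4511 against 0.0177 FPKM (-12.11), and Cd74, the MHC class II invariant chain, at 2512 against 0.00444 FPKM (-11.29). Scgb1a1, the club cell secretoglobin, was detected in 32 of 34 lineage- and 18 of 50 lineage+ cells. It was also detected in 11 of 11 immune-like lineage- cells. Its log2 ratio was -9.54, and -5.38 over cells with an estimated 2000000 reads or more. Cbr2, Sec14l3, Lyz1, Napsa, Mal2, Sftpb and Cyp2f2 completed the 12 with log2 ratios from -10.15 to -6.45. Where a group's mean lies far below 1 FPKM, the ratio is set mainly by the 1 FPKM added to both groups. Cyp2f2 moved from -6.45 to -3.19 without the well described as debris (lineage- cell 23), and without the highest cell of each group Cd74 moved to -10.46, Napsa to -7.08, Mal2 to -6.65 and Cyp2f2 to -4.03. Of the 24 genes chosen by that rule, 19 moved by more than 1.5-fold among cells with at least 2000 genes. With cells scaled to a common total 16 moved, and with the mean of log2 values 20. With 0.1 and 10 FPKM added 14 and 24 moved. None changed direction under these settings.

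**Figure D3:**
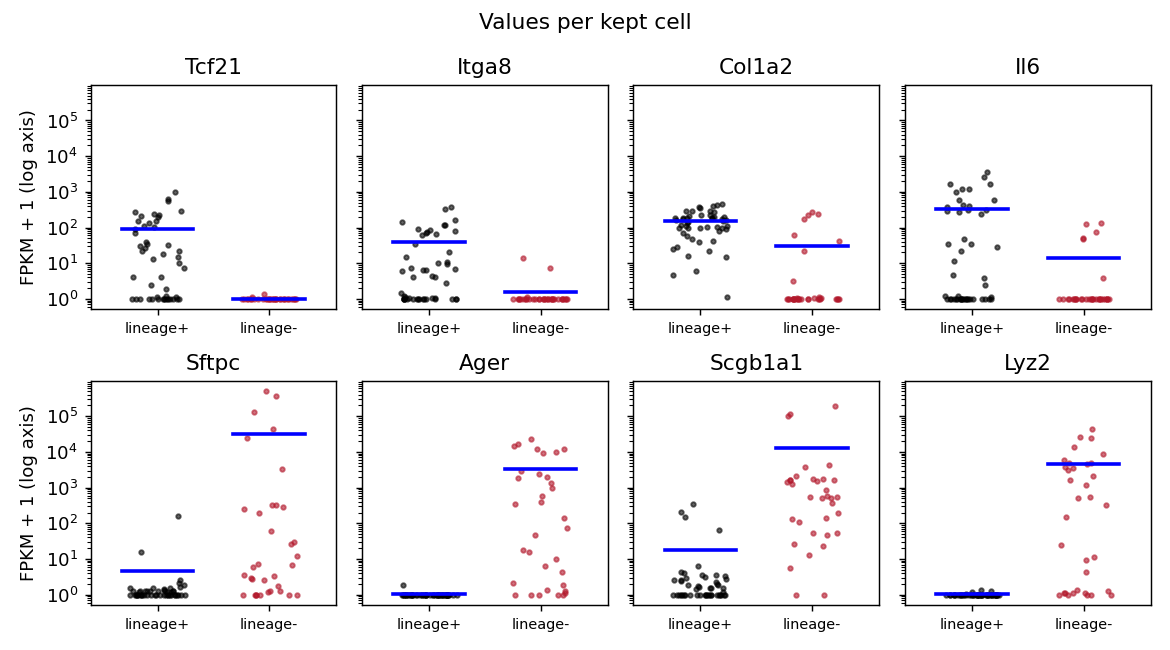
FPKM plus 1 (log axis) of 8 genes in each kept cell, lineage+ in black and lineage- in red, with the group mean as a blue bar. Tcf21, Itga8, Col1a2 and Il6 have the higher mean in lineage+ cells, and Sftpc, Ager, Scgb1a1 and Lyz2 in lineage- cells.

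Marker lists differed as whole groups. Counts are of members detected in at least 10% of the cells of either group, called higher or lower where the group means differ at least 2-fold. By that count all 10 alveolar type 2 markers, all 7 type 1 markers, all 5 airway markers, all 6 general epithelial markers and all 9 immune markers were at least 2-fold higher in lineage- cells. Their median log2 ratios were -7.59, -6.14, -5.07, -3.45 and -6.98, and none lay above the 0.05th percentile of 10000 random lists matched on mean expression. Among type 2 markers Sftpa1 stood at 1089 FPKM in lineage- cells. Among immune markers Tyrobp stood at 521 FPKM in lineage- against 2.34 FPKM in lineage+, and Cd52 at 273 FPKM while listed at 0 in lineage+ cells. In the other direction, 7 of 11 alveolar fibroblast markers were at least 2-fold higher in lineage+ cells and 1 was lower (median 2.59, 100th percentile). Spon1 stood at 109 against 9.61 FPKM. Of 13 adventitial fibroblast markers 12 were higher (median 1.65, 99.9th percentile), with Clec3b at 46.9 against 5.17 FPKM. All 4 myofibroblast markers so detected, of 8 measured, were higher (median 2.35, percentile 98.85), as were 5 of 6 pericyte markers (2.33, percentile 98.85) and 9 of 11 mesothelial markers (1.89, 99.9th percentile), among them Upk1b at 150.0 against 1.81 FPKM. The mesothelial marker Krt19, which epithelium also expresses, was lower, at 27.6 against 108 FPKM. Of 15 endothelial markers 4 were so detected, Kdr, Tek, Calcrl and Eng, in 5 to 9 of 50 lineage+ cells, and 3 were higher (1.64, percentile 97.7), Tek at 7.43 against 0.269 FPKM. These 4 genes lie outside the rule for named genes and were chosen after their values were seen. Of 10 smooth muscle markers 3 were so detected, all higher (2.34), and at percentile 97.25 the list did not stand apart. It did under 4 alternatives, among them without the highest cell of each group (2.52). Kdr, Eng and the smooth muscle gene Des, also chosen after its values were seen, were each detected in 5 of 50 lineage+ cells, just the 10% needed. Both lists gave no median when the repeated profiles were counted separately. Among cells with at least 2000 genes the adventitial, pericyte, endothelial and general epithelial lists no longer stood apart from random lists, with medians of 0.29, 1.69, 1.79 and -0.29. That set kept 3 of the 19 epithelial-like lineage- cells but all 3 fibroblast-like ones, so the mix of classes changed too. The mesothelial list did not stand apart with the mean of log2 values (1.59) or with members detected in 25% of cells (1.38), nor the pericyte list with 10 FPKM added (0.71). The endothelial list also lost this with the mean of log2 values (0.53), 10 FPKM added (0.32) and no filter on detection (0.000389). Neural and erythroid lists had fewer than 3 members detected in 10% of cells and gave no median.

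Among extracellular matrix lists, those of fibrillar collagens, elastic fibre and proteoglycans were higher in lineage+ cells, while the basement membrane list did not stand apart. Of the 12 genes in the fibrillar collagen list, the 11 detected in at least 10% of cells were all at least 2-fold higher (median 1.86, percentile 99.9), but did not stand apart among cells with at least 2000 genes (1.00). Col1a2, a chain of type I collagen, was detected in 49 of 50 lineage+ and 8 of 34 lineage- cells, at 154 against 30.1 FPKM, and Col6a2 stood at 41.6 against 2.45 FPKM. Of 13 elastic fibre genes 11 were higher (2.06, percentile 99.97), with Lox, a collagen and elastin crosslinking enzyme, at 6.91 against 0.0666 FPKM. Of 10 proteoglycan and hyaluronan genes 8 were higher (2.18, percentile 99.99), with Bgn at 832 against 113 FPKM. The complement list had the largest median of the pathway lists (2.39, percentile 99.98), with 8 of 9 genes higher. Serping1, the C1 inhibitor, stood at 1249.8 against 192 FPKM and was detected in 50 of 50 lineage+ and 8 of 34 lineage- cells. Basement membrane genes went both ways (median 0.71, percentile 84.5), Lama2 at 21.4 against 1.73 FPKM and Col4a3 at 16.8 against 187 FPKM, and stood apart with the mean of log2 values (1.08).

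**Figure D4:**
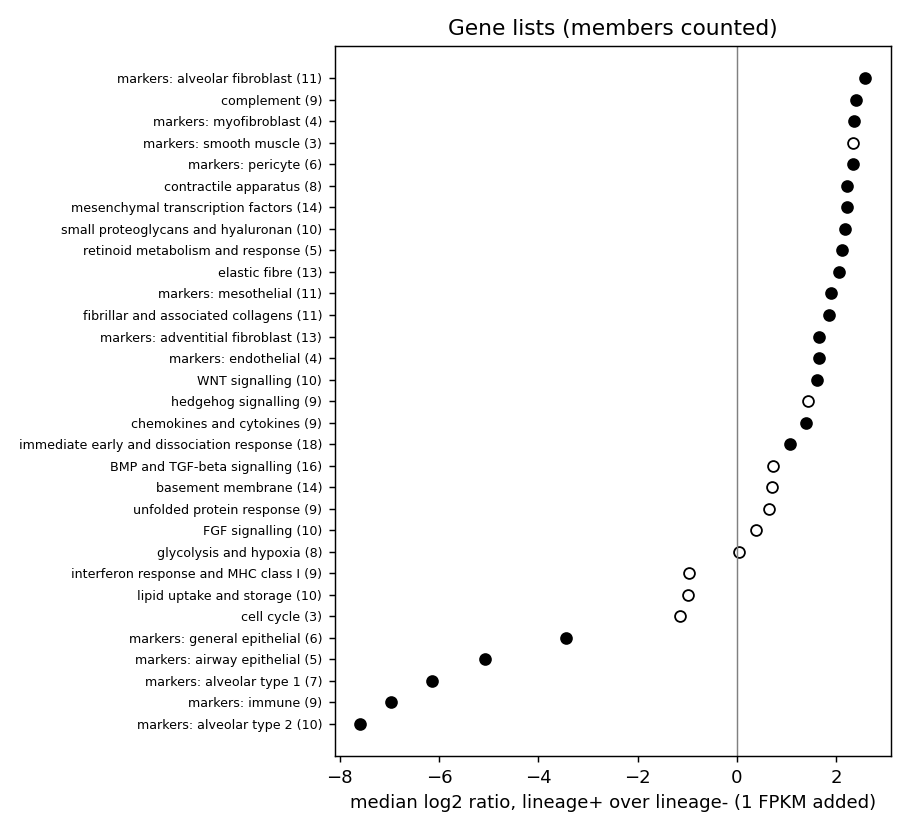
Median log2 ratio of lineage+ over lineage- (1 FPKM added) for each list with at least 3 members detected in 10% of cells, whose number is in brackets, with filled points for lists outside the central 95% of random lists. Type 2 markers lie lowest at -7.59 and alveolar fibroblast markers highest at 2.59.

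Regulatory and signalling lists were mixed. Of 14 mesenchymal transcription factors 9 were at least 2-fold higher in lineage+ cells and 0 lower (median 2.21, 100th percentile), including Foxf1, a forkhead factor of lung mesenchyme, at 17.3 against 0.0476 FPKM. Among cells with at least 2000 genes that median was 0.78 and no longer stood apart. The retinoid list (2.12, percentile 99.5), with 4 of 5 genes higher, included Lrat, which esterifies retinol, at 36.1 against 0.00129 FPKM. The contractile list (2.23, percentile 99.85), with 7 of 8 higher, included Mylk at 57.8 against 8.78 FPKM. The WNT list (1.61, percentile 99.1) had 6 genes higher and 1 lower, with Dkk3 at 53.1 against 2.69 FPKM. The contractile and WNT lists did not stand apart among cells with at least 2000 genes (1.48 and 1.35) or with members detected in 25% of cells (1.62 and 0.77), nor did WNT with no filter on detection (0.65). Hedgehog (1.43, percentile 94.3), BMP and TGF-beta (0.73, percentile 90.7) and FGF (0.39, percentile 72.9) lists did not stand apart with the settings fixed for the comparison. Hedgehog did under 5 alternatives, among them without the highest cell of each group (2.10), BMP and TGF-beta under 3, among them cells with at least 2000 genes (1.41), and FGF with the mean of log2 values (1.61). Within the FGF list Fgf10, a growth factor for epithelium, stood at 21.8 against 0.475 FPKM, and its receptor gene Fgfr2 at 0.682 against 22.6 FPKM.

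Stress and housekeeping lists were examined for signs of handling. The groups hold different cell classes, so a difference in these lists cannot be told apart from a difference between classes. The immediate early and dissociation list was higher in lineage+ cells (median 1.07, percentile 99.8), 10 of its 18 genes being at least 2-fold higher and 2 lower. Egr1 stood at 1231 against 297 FPKM and Jund at 5.90 against 43.8 FPKM, the latter turning to 0.23 in log2 ratio over cells with an estimated 2000000 reads or more. The chemokine and cytokine list had 7 of 9 genes higher and 1 lower (1.40, percentile 98.5). Among cells with at least 2000 genes neither list stood apart (medians 0.28 and 0.22), and with the mean of log2 values the chemokine list did not (1.49). The unfolded protein (0.66, percentile 88.9), glycolysis (0.0352, percentile 53.6), interferon and MHC class I (-0.96, percentile 4.59), lipid (-0.98, percentile 4.32) and cell cycle (-1.15, percentile 15.2) lists did not stand apart with those settings. The lipid list did under 4 alternatives, among them cells with at least 2000 genes (-1.51), and the cell cycle list under 3, among them all 91 cells (-2.04). Scd1, a fatty acid desaturase in the lipid list, stood at 7.80 against 463 FPKM, and G0s2 at 164 against 18.4 FPKM. Of the sex chromosome genes, Xist was detected in 40 of 50 lineage+ and 29 of 34 lineage- cells, while Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 or under 1 FPKM in every kept cell. The mitochondrially encoded list had 0 measured members.

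The comparison within a class needed at least 5 cells in each group. Fibroblast-like cells numbered 40 and 3 and mesothelial-like cells 10 and 1, so no class met it and no such comparison was made. For every gene and list above, a difference between the groups therefore cannot be told apart from their different mix of cell classes.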

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

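All tests in this part were chosen after the result they measure had been seen. Groups of more than 10 cells were not examined for single outlying cells. Signals in 5 of the 7 cells left out for few genes exceeded the highest value of the same gene in any kept cell. Lineage- cell 36 had S100a8, a neutrophil calprotectin gene, at 56707 FPKM against at most 4.20 in kept cells, and lineage- cell 33 had S100a9 at 12603 FPKM against at most 1.32. Lineage- cell 32, with an estimated 51600 reads, had Scgb1a1 at 613774 FPKM, 84.8% of its total, against at most 196038 in kept cells. Small nucleolar RNA rows led the other two, Snora30 at 60481 FPKM in lineage- cell 11 (at most 9198 in kept cells) and Snora81 at 38462 FPKM in lineage- cell 22 (at most 29716).

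The lineage- sort held mostly cells with epithelial or immune profiles, although the series design calls it mesenchymal. The gate as written is positive for Epcam, which would admit epithelial cells, and excludes CD45. Free RNA from lysed cells would keep epithelial and immune transcripts in about 1 ratio in every well. The log2 ratio of summed epithelial to immune marker FPKM had an interquartile range of 7.66 over the 34 kept lineage- cells. This spread cannot decide on free RNA. The epithelial-like and immune-like classes were themselves named from these markers, so some spread between them was already given. The sum also includes Sftpc, whose listed values are questioned below. Free RNA therefore stays open. Shallow libraries cannot account for the cells of these classes that were not shallow. Of 28 lineage- cells with an estimated 2000000 reads or more, 24 were in these classes (85.7%, exact 95% interval 67.3 to 96.0%). Only 6 of the 34 kept lineage- cells lay below that depth. This share could therefore not have come out low, and it says nothing on those 6 cells. The sort gate, the chip, the animal or preparation and the lineage itself stay open and cannot be told apart, since each group has a name prefix of its own and no label names a chip or an animal.

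Sftpc was listed at exactly 0 in lineage- cells that carried many other type 2 markers. Of 10 lineage- cells with at least 6 of the 9 other type 2 markers, 6 (60%, 26.2 to 87.8%) had Sftpc at 0, against 1 of 24 other lineage- cells (4.17%, 0.105 to 21.1%). A failed estimate for a very abundant transcript is a candidate explanation, since it predicts zeros where the gene should be highest. Sftpc had a value in lineage- cell 1 at an estimated 961768 reads, the most listed for any gene and cell. The abundance of Sftpc in the cells at 0 is not known and may be higher. That value therefore cannot count for or against a failed estimate. Shallow sequencing is argued against: the median estimated depth of the cells at 0 was 3.13 times that of the cells above 0, 9410000 against 3010000 reads. No biological explanation was tested.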

How the results depend on the processing

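The alternatives were fixed before the data were examined, except the cells with an estimated 2000000 reads or more, the repeated profiles counted separately and the classes called per cell from markers. No paired analysis was possible because each replicate number names a cell, not an animal. Thinning of reads and TMM scaling need counts and were not run, and no class had enough cells for the comparison within a class. With the repeated profiles counted separately, all 124 named genes stayed within 1.5-fold, class shares stayed within their intervals and no list with a median there changed its call, while the endothelial and smooth muscle lists gave no median. Class shares also stayed within their intervals under resolutions 0.5 and 2, 1000 variable genes, 8 components, all 91 cells, without the debris well, with 2000000 reads or more and per cell, where 5 of the 11 immune-like cells became epithelial-like and the immune-like share of lineage- cells was 17.6%. With all 91 cells, 24 of 39 lineage- cells were epithelial-like and 11 immune-like. All 5 added lineage- wells were thus named epithelial-like, among them lineage- cell 36, led by the immune marker S100a8. The shares in that setting therefore do not check the naming of the added wells. Ward clustering gave lineage+ cells as 100% fibroblast-like and 0% mesothelial-like, and lineage- cells as 0% mesothelial-like. Each group on its own gave 40% (lineage+) and 0% (lineage-) fibroblast-like, where 9 lineage+ cells became pericyte- and smooth muscle-like and 11 stayed unnamed, and mesothelial-like lineage- cells rose from 1 to 5 of 34 (14.7%). Of 12 lineage- cells with at least 2000 genes (median 2562) 0% were epithelial-like and 75% immune-like, since 3 epithelial-like and 1 fibroblast-like cells joined an immune-like cluster.

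Detection above 0 raised the median of genes to 4129 (lineage+) and 3558 (lineage-), Epcam in lineage- to 64.7% and Pdgfrb in lineage+ to 52%. Detection at 10 gave 1535 and 1130 genes, Epcam 14.7% and Pdgfrb 0% of lineage- cells. These follow from the threshold itself.

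Lists that stood apart lost this among cells with at least 2000 genes for WNT (1.35), chemokines (0.22), contractile (1.48), immediate early (0.28), adventitial (0.29), general epithelial (-0.29), pericyte (1.69), endothelial (1.79), fibrillar collagens (1.00) and mesenchymal factors (0.78). They lost it with the mean of log2 for chemokines (1.49), mesothelial (1.59) and endothelial markers (0.53), with 10 FPKM added for pericyte (0.71) and endothelial markers (0.32), with members in 25% of cells for WNT (0.77), contractile (1.62) and mesothelial markers (1.38), and with no filter for WNT (0.65) and endothelial markers (0.000389). The cut at 2000 genes also changed the mix of lineage- cells. It kept 3 of the 19 epithelial-like cells, but all 3 fibroblast-like cells and the 1 mesothelial-like cell. The cause of these losses was not tested. Lists came to stand apart for hedgehog with the mean of log2 (1.15), without the highest cell (2.10), with 10 FPKM added (0.66), no filter (1.29) and members in 25% of cells (1.93). Smooth muscle did with cells scaled to a common total (3.79), without the highest cell (2.52), with 0.1 FPKM added (5.38) and no filter (0.69). Lipid did with all 91 cells (-1.38), at least 2000 genes (-1.51), the mean of log2 (-0.61) and without the highest cell (-0.84). Cell cycle did with all 91 cells (-2.04), 2000000 reads or more (-2.28) and no filter (-1.41), BMP and TGF-beta with at least 2000 genes (1.41), 2000000 reads or more (1.23) and without the highest cell (1.57), and basement membrane (1.08) and FGF (1.61) with the mean of log2. No call for a list reversed.

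Log2 ratios changed sign with all 91 cells for Eno1 (-0.39) and Ptp4a1 (-0.63). Among cells with at least 2000 genes they did so for Acta2 (-0.000803), B2m (-0.0595), Boc (-0.17), Entpd2 (-0.11), Epcam (1.48), Myl9 (-0.47), Pcna (0.28), Sfrp1 (-0.52), Tppp3 (0.83), Wnt4 (-0.0427) and Xbp1 (-0.65). With 2000000 reads or more they did so for Jund (0.23) and Pcna (1.06), with the mean of log2 for Fzd1 (0.93), H2-D1 (0.19), Pcna (0.54), Pfkp (0.25) and Tyms (0.24), and without the highest cell for Fzd1 (0.46) and Pcna (0.12). The cause was not tested. Over all settings but the common shift, which moves every gene alike, 829 ratios of named genes stayed within 1.5-fold, 389 moved by more with the same direction and 22 reversed, while 229 medians of lists that stood apart still did and 21 medians of other lists came to. The 6 lineage- cells under an estimated 2000000 reads are the shallowest, and what depth hides in them was not tested.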

Other observations

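The marker minimum of 4 and all values of rho but the first were chosen after seeing the data, and the bounds for free RNA and for a pair of cells in 1 well before. Most lineage+ fibroblast-like cells carried markers of both the alveolar and the adventitial fibroblast lists. Of 40 lineage+ fibroblast-like cells, with repeated profiles counted once, 27 (67.5%, exact 95% interval 50.9 to 81.4%) detected at least 4 markers of both lists, 7 of the alveolar list alone and 6 of the adventitial list alone, with medians of 6 and 7 markers. In the mesothelial-like class 6 of 10 lineage+ cells also detected at least 4 adventitial markers. Of 19 epithelial-like lineage- cells, 8 detected at least 4 type 2 markers alone, 6 at least 4 type 1 markers alone, and 4 both. These counts are not comparable between classes, since the lists differ in size and the cells in genes detected.

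The 3 lineage- fibroblast-like cells had a mean Col1a2 of 242 FPKM, and the 40 lineage+ fibroblast-like cells of 174 FPKM. Tcf21 did not reach 1 FPKM in any of these 3 cells, and did so in 31 of 50 lineage+ cells of all classes. Itga8 stood at 12.6 and 6.21 FPKM in lineage- cells 4 and 10 and at 0 in lineage- cell 20. Against a median of 6 alveolar fibroblast markers in lineage+ fibroblast-like cells, these 3 cells detected 6, 6 and 5. Lineage- cell 10 among them also carried immune markers, and all 3 lay in a cluster that held 25 of the 40 lineage+ cells. They number too few for a comparison within the class.

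Wells counted as mixed detected at least 40% of a list's measured markers, and at least 5, in more than 1 broad class. By that cutoff 5 lineage- wells and 6 lineage+ wells were mixed, the latter all mesothelial-like with fibroblast markers. Wells below it can still carry markers of another class, as lineage- cell 2 did with 7 type 1 and 5 immune markers. The tests were run on the lineage- wells. Scgb1a1 was detected in 11 of 11 immune-like cells, at a median of 199 FPKM against 1260 FPKM in epithelial-like cells. It was also detected in 3 of 3 lineage- fibroblast-like cells (median 529 FPKM) and in the 1 lineage- mesothelial-like cell (517 FPKM). Among lineage+ cells 12 of 40 fibroblast-like (median 0.102 FPKM) and 6 of 10 mesothelial-like cells (median 1.44 FPKM) detected it. Free RNA among the lineage- cells may contribute. Across 36 epithelial markers, which are not independent replicates, their means in immune-like and epithelial-like cells had a Spearman rho of 0.88, and 0.39 when lineage+ fibroblast-like cells took the place of the immune-like cells. A few cells carry the means in immune-like cells, such as Sftpc with a mean of 2321 and a median of 5.58 FPKM, and rho fell to 0.44 with medians. Of the 11 immune-like cells 5 were called epithelial-like from their own markers, and over the other 6 rho was 0.77 for means and 0.47 for medians. In the immune-like cells free RNA, cells named wrongly by the clustering and a pair of cells in 1 well therefore cannot be told apart. Naming epithelial cells immune-like would not place Scgb1a1 in the lineage- fibroblast-like and mesothelial-like cells, where no such test was run. The 5 mixed lineage- wells had 1.46 times the median of genes detected in the other 29 (2619 against 1797). That exceeds the bound set beforehand for a pair of cells in 1 well. A well with more genes detected also passes a marker cutoff more easily, so this ratio cannot decide between these explanations.

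The near-identical lineage+ profiles came from capture sites whose numbers differ by 12 in both pairs, 47 and 35 for cells 2 and 15, and 41 and 29 for cells 9 and 23. Whether material of 1 cell was carried into a second library, or 1 library was read again, was not tested.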
